A study of Mus musculus with 6 samples.

How the data were processed

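RNA from dorsal root ganglia was measured in 6 libraries, 3 from mice fed ad libitum and 3 from mice on 10 days of intermittent fasting. Per the labels' protocols, ganglia at L4-6 were dissociated with Dispase II (1 mg/ml), Collagenase Type II (2.5 mg/ml) and papain, neurons were enriched on a 15% BSA gradient, and libraries were made with a stranded kit that selects polyadenylated RNA. Per the labels the animals were killed after 24 hours, without a statement of what the 24 hours follow. Groups and replicate numbers were taken from the labels.

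The deposited values are TPM per transcript, made by the authors. Per the submitters' processing notes, FastQC 0.11.9, Trim Galore 0.6.6, Salmon 1.6.0 and DESeq2 1.34.0 were used with the builds GRCm38 and mm10; the annotation release is not given in the sources used here, and neither are the roles or order of these tools. The table holds 140992 transcripts, and each library sums to 1000000. TPM divides by transcript length and by the library total, so it is a share of transcripts and not of RNA mass: a rise of some transcripts lowers all others, and the depth is lost. For this reason no count test was run, and the precision of low values cannot be given.

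TPM was summed over transcripts with the same gene symbol (54242 symbols; 102 symbols had 2 or more gene identifiers and were summed), and genes with a mean of at least 1 TPM over all 6 libraries were kept (15097). Values were analysed as log2(TPM + 1), a pseudocount of 1, so fold changes are on that scale and understate the change of low genes. Coordinates, gene types and lengths came from GENCODE release M21 (GRCm38), in which 98.7% of the deposited transcript versions were found. Fasted and fed libraries were compared with limma 3.58.1 in R 4.3.3 (a linear model per gene with group as the only term, empirical Bayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. No replicate block was used, since no label ties a replicate number to a shared litter, batch or day.

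Before the data were examined, 40 gene lists were fixed: pathways (leptin and JAK-STAT, regeneration-associated, hormone receptors, PPAR-alpha, FoxO, glucocorticoid, clock, cholesterol and fatty acid synthesis, integrated stress, unfolded protein and heat shock responses, interferon, cytokines, MHC class II, autophagy, oxidative phosphorylation, cell cycle, neuropeptides, channels), library quality (immediate early, mitochondrial, ribosomal) and cell types (neuronal, glial, immune, erythrocyte, vascular, fibroblast, adipocyte, muscle). Each list with at least 3 tested members was compared with the other genes by limma's camera with a preset correlation of 0.01, adjusted over the 40 lists. Lists were also tested with an estimated correlation and, as an alternative chosen after seeing the data, with fry, which tests whether the members move one way and does not compare them with other genes. Library scores of lists are means of log2(TPM + 1) after centring each gene, compared by exact permutation tests. Symbols of the lists were matched to the table directly or, for 2, through gene identifiers; 1 was not matched.

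The genes named were fixed by rule before the data were examined: genes past the threshold without overlap between groups, topped up to 12 per direction by the smallest p among genes without overlap, with predicted and clone names counted but not named; 12 genes fixed by name; the 4 members with the smallest p in the direction of each list that passed; and up to 2 members of each other list. Gm23257, Arntl, Nr1d1, Klf9, Sgk1, Plin4, Bc1 and mt-Co2 fall outside this rule and were named after their values were seen. The tests were tried on 10 simulated data sets with the 15097 genes of this comparison. In these, 72.5% of genes changed 1.5-fold and 90.5% of those changed 2-fold were called, 5.4% of calls were false, 1 of 400 unchanged lists was called, and 10 of 10 lists lowered by 0.33 were called. The simulated genes were independent, unlike real ones. Changed genes and lowered lists were drawn only from genes above about 5 TPM. The shares called thus do not hold for genes below that, such as Lepr. Many genes were changed at once in each simulated set, which makes the adjusted threshold easier to pass than when few change. In the real data 1 gene passed, so these shares do not tell how many changes of such sizes were missed here.

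Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 TPM, median-of-ratios, TMM-type and quantile scaling, rescaling without mitochondrial genes, robust and untrended empirical Bayes, array weights, a replicate block, an estimated correlation in camera, and leaving out each library; protein-coding genes alone and fry were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.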

Results

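Messenger RNA was measured in dorsal root ganglia (DRG), the clusters of sensory neuron cell bodies beside the spinal cord, taken at the levels L4-6 from male C57bl/6 mice of 8-10 weeks. The animals had either eaten freely (ad libitum, called fed here) or followed 10 days of intermittent fasting (called fasted). The ganglia were dissociated with enzymes and passed through a BSA gradient to enrich neurons, and the share of RNA from other cells was not measured. There were 6 libraries, 3 fed and 3 fasted, and 1 comparison, fasted against fed. No label states whether a replicate is 1 animal or a pool, so the p-values measure the spread between these libraries, which may be technical in part. Values are TPM, the share of transcripts scaled to 1000000 per library. TPM keep no sequencing depth, so the depth behind each value is unknown and no counting interval is given. Of 54242 gene symbols, 15097 had a mean of at least 1 TPM over the 6 libraries and were tested. Between 14961 and 15218 genes reached 1 TPM in each library.

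The libraries were alike in rank order, with Spearman correlations across genes from 0.983 to 0.992; genes are not independent replicates. Fed replicate 2 stood apart on the first principal component, which held 32.8% of the variance, at -31.2 against -1.38 to 17.7 in the other libraries. On its side of that component, skeletal muscle genes had the largest loadings. One muscle gene, Ckm (muscle creatine kinase), was at 490.0 TPM in that library against 9.07 to 52.2 in the other 5. The same library drew 8.86% of its TPM from the 13 mitochondrially encoded protein genes, against 5.62% and 6.79% in the other fed libraries and 4.74% to 5.15% in the fasted ones. Fasted replicate 3 held the most haemoglobin RNA, with Hba-a2 at 1280.5 TPM against 456.6 to 923.9 elsewhere. The non-coding RNA Bc1 was the most abundant gene in 5 libraries, and mt-Co2 in fed replicate 2.

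The title of the series concerns leptin signalling and axon regeneration, and the first question here is whether fasting shifted the leptin pathway in the ganglia. Lepr, the leptin receptor (chromosome 4, 101717404 to 101815352, GRCm38), lay at 3.63 ± 0.58 TPM in fed and 3.48 ± 0.50 TPM in fasted libraries (SD, n = 3 each). Its log2 fold change was -0.05 with a standard error of 0.13, and ran from -0.14 to 0.06 when each library was left out in turn. The transducers Jak2 (12.8 ± 1.14 against 12.2 ± 0.71 TPM) and Stat3 (168.5 ± 8.53 against 175.7 ± 4.6 TPM) and the feedback inhibitor Socs3 (6.97 ± 1.499 against 7.17 ± 0.50 TPM) overlapped between the diets. Lep itself averaged 0.17 TPM over the 6 libraries and was below the limit for testing. Of the 26 tested members of the leptin and JAK-STAT list, 15 were higher and 11 lower in fasted libraries, and 0 passed, adjusted over the list alone or over all genes. On TPM, 62.5% of all tested genes were higher in fasted libraries, so such counts are not to be read against an even split. The members with the smallest p were Jak1 (190.3 ± 9.18 against 205.6 ± 8.90 TPM) and Leprotl1 (135.3 ± 7.54 against 144.2 ± 3.46 TPM). The list as a whole did not pass (limma's camera, adjusted p = 0.86). Its median (0.03) and mean (0.02) were positive while the test, which sets it against the other genes, pointed down; without fasted replicate 2 the median was -0.0022.

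Regeneration-associated genes, which sensory neurons switch on after axon injury, were compared next. Gap43 lay at 269.3 ± 23.9 against 266.4 ± 4.42 TPM, Sox11 at 2.03 ± 0.59 against 1.82 ± 0.17 TPM, Gal at 38.5 ± 6.83 against 39.5 ± 6.27 TPM and Npy at 1.37 ± 0.90 against 1.20 ± 0.62 TPM (SD, n = 3 each). Atf3, an injury-induced transcription factor, was at 13.0, 18.0 and 6.22 TPM in fed and 6.70, 6.03 and 8.03 TPM in fasted libraries (limma, adjusted p = 0.52). Sprr1a was at 6.58, 15.9 and 0.60 TPM against 0.49, 0.74 and 1.73 TPM (limma, adjusted p = 0.52). Jun was at 64.1 ± 2.07 against 70.3 ± 1.336 TPM (limma, adjusted p = 0.48). As a list, the 32 tested members passed in the lower direction (limma's camera, adjusted p = 0.021), with a median of -0.02 and a mean of -0.18. The adjusted p was 0.77 with an estimated correlation. One member, Csrp3, passed when adjusted over the list alone, and 0 over all genes. Csrp3 codes for a muscle LIM protein and was at 1.23, 4.04 and 2.51 TPM in fed replicates 1, 2 and 3 and at 0, 0.24 and 0.39 TPM in the fasted ones. The 4.04 TPM is from the library with the most muscle RNA. Anxa1 (9.64 ± 0.41 against 7.69 ± 1.15 TPM) and Gpr151 (1.94 ± 0.52 against 1.25 ± 0.11 TPM) followed it. The call was lost without fed replicate 1 (adjusted p = 0.17, median 0.01), fed replicate 2 (0.89, median 0.02) or fasted replicate 1 (0.14, median -0.0084). The median was -0.09 without fed replicate 3, -0.03 without fasted replicate 2 and -0.04 to -0.05 under the scalings tried. The call was also lost with a minimum of 5 TPM (adjusted p = 0.089) or array weights (0.057).

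**Figure D1:**
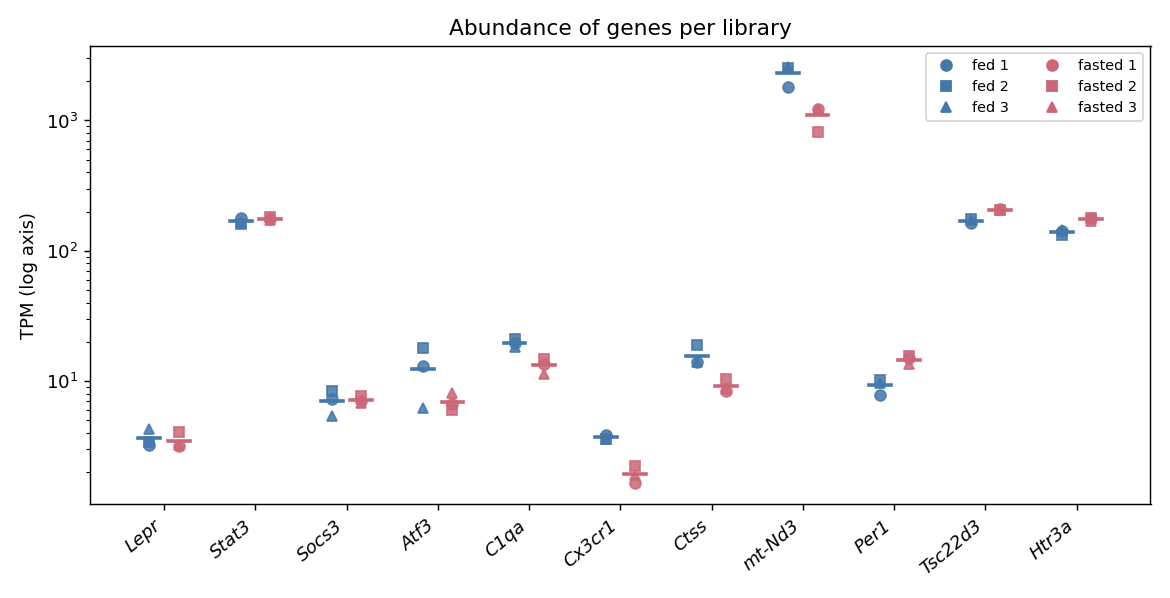
Abundance in TPM (log axis) of 11 genes in the 3 fed and 3 fasted libraries, with points for libraries and bars for group means. Lepr, Stat3, Socs3 and Atf3 overlap between diets, while C1qa, Cx3cr1, Ctss and mt-Nd3 lie lower, and Per1, Tsc22d3 and Htr3a higher, in all fasted libraries.

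Gene by gene, few differences stood clear of the replicate spread. One gene of 15097 passed an adjusted p of 0.05: Gm23257, higher in fasted libraries at 11.1 ± 1.61 TPM against 1.70 ± 0.26 TPM (SD, n = 3 each; log2 fold change 2.16, standard error 0.12; limma, adjusted p = 0.0044). It is a predicted name and was singled out after its values were seen. Without a filter on low values, where more genes are tested, it did not pass (adjusted p = 0.053). The annotation places it at chromosome 4, 43692686 to 43692817 (GRCm38), as an rRNA gene of 132 bases. Such short repeated sequences share reads with copies elsewhere, so its abundance is uncertain. Tested alone with limma, 0 of the 13585 protein-coding genes passed; the smallest adjusted p was 0.27, and 980 higher and 464 lower had an unadjusted p under 0.05. Without the adjustment, 1501 genes had p under 0.05, 1015 higher and 486 lower, where chance gives 755. This split followed the scaling, with 567 higher and 733 lower under median-of-ratios scaling, 573 and 728 under TMM-type scaling, 663 and 661 under quantile normalization, and 557 and 756 with mitochondrial genes left out. With 1 library left out, the counts ran from 596 to 1188 higher and from 381 to 617 lower. The fasted and fed values did not overlap for 2687 genes, 17.8% of those tested, where chance gives 10%. Of these, 1922 were higher and 765 lower in fasted libraries. This count was made on TPM only, so its excess of higher genes may follow the scaling too.

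The genes with the smallest p among those without overlap were named by a fixed rule, and none of the 24 passed. Higher in the 3 fasted libraries were Htr3a, a serotonin-gated ion channel (139.0 ± 6.72 against 175.1 ± 4.38 TPM), Tsc22d3, a glucocorticoid-induced gene (170.3 ± 6.01 against 206.5 ± 3.04 TPM), Mat2a, which makes S-adenosylmethionine (121.3 ± 1.30 against 141.7 ± 0.31 TPM), and the small GTPase gene Rhob (110.4 ± 0.66 against 127.8 ± 1.08 TPM). Also higher were Per1, Ltbp4, Mocs1, Ip6k2, Erg28 and Tmem267, with log2 fold changes from 0.22 for Ip6k2 to 0.61 for Per1. Mir6538 was listed at 0 in the fed libraries and at 12.7, 5.81 and 4.86 TPM in the fasted ones (limma, adjusted p = 0.092). It is annotated as a miRNA gene of 110 bases, in libraries selected for polyadenylated RNA, so its abundance is uncertain, like that of Gm23257. Lower were the interferon-induced Oasl2 (48.5 ± 2.56 against 33.7 ± 2.19 TPM, log2 fold change -0.51), the microglia and macrophage receptor gene Cx3cr1 (3.69 ± 0.15 against 1.92 ± 0.30 TPM, -0.69), the complement gene C1qa (19.7 ± 1.33 against 13.2 ± 1.71 TPM, -0.55) and the lysosomal protease gene Ctss (15.6 ± 2.73 against 9.11 ± 1.05 TPM, -0.71). Olfr1033, Fbln5, Rhoj, Upp2, Arap1, Grrp1, Casp4 and mt-Nd3 made up the rest, from -0.24 for Fbln5 to -1.08 for mt-Nd3. For the protein-coding genes named here, the smallest adjusted p was 0.28 (limma).

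Macrophage, MHC class II, interferon-responsive and endothelial genes were lower in fasted libraries. Macrophage markers fell as a list, with a median log2 fold change of -0.33 (limma's camera, adjusted p = 1.9e-14, but adjusted p = 0.45 with an estimated correlation). Of 18 markers 17 were lower, 7 of them passing when adjusted over the list alone, among them Cx3cr1, C1qa, Ctss and Cd68 (3.34 ± 0.06 against 2.28 ± 0.23 TPM). MHC class II genes, which present antigen, fell by a median of 0.37 (adjusted p = 3.8e-06; adjusted p = 0.45 with an estimated correlation). Of these, 4 of 6 passed when adjusted over the list alone: H2-Aa (58.7 ± 4.58 against 41.6 ± 5.96 TPM), H2-Ab1 (43.6 ± 3.01 against 32.1 ± 3.40 TPM), H2-Eb1 and Cd74. Interferon-responsive genes fell by a median of 0.19 (adjusted p = 1.4e-11; adjusted p = 0.45 with an estimated correlation), with 25 of 25 lower. Passing when adjusted over the list alone were 2, Oasl2 and Ifi27l2a (53.5 ± 8.71 against 31.6 ± 5.06 TPM); Irf7 and Usp18 came next. Fasted replicate 3, which held the most haemoglobin RNA, had an interferon score of -0.32 against -0.04 and -0.02 in the other fasted libraries, and without it the median was -0.13. Endothelial markers fell by a median of 0.22 (adjusted p = 1.2e-09; adjusted p = 0.45 with an estimated correlation), with 15 of 16 lower. Of them 5 passed when adjusted over the list alone, including Sox17, Sox18, Emcn and Ly6c1. Fed replicate 2, with its muscle RNA, had the highest macrophage score (0.30 against 0.14 and 0.08 in the other fed libraries) and the highest endothelial score (0.23 against 0.02 and 0.05). Without it the endothelial median was -0.12, and without fasted replicate 1 it was -0.14. None of these members passed when adjusted over all genes.

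Mitochondrially encoded genes were lower together. All 13 were lower in fasted libraries, with a median log2 fold change of -0.49 (limma's camera, adjusted p = 1.0e-14; adjusted p = 0.45 with an estimated correlation). When adjusted over the list alone 11 passed, and 0 over all genes. Complex I genes had the smallest p: mt-Nd3 was at 2308 ± 437.8 against 1092 ± 233.5 TPM, mt-Nd5 at 2026 ± 364.2 against 1433 ± 74.1 TPM, mt-Nd1 at 4907 ± 950.5 against 3443 ± 111.4 TPM and mt-Nd2 at 3400 ± 709.6 against 2327 ± 94.3 TPM (SD, n = 3 each). The list score was 0.61 in fed replicate 2, which held the most muscle RNA, -0.05 and 0.24 in the other fed libraries and -0.32 to -0.23 in the fasted ones. The 60 nuclear-encoded genes of oxidative phosphorylation did not pass (median 0.02, adjusted p = 0.88), with Ndufb2 at 354.2 ± 8.94 against 326.7 ± 8.75 TPM and Ndufs3 at 174.2 ± 5.30 against 188.0 ± 5.36 TPM. Cytosolic ribosomal protein genes fell by a median of 0.06 (adjusted p = 1.0e-14; adjusted p = 0.54 with an estimated correlation), with 68 of 76 lower and 0 passing when adjusted over the list alone. Rps12 (419.4 ± 20.6 against 346.7 ± 27.0 TPM), Rps19 and Rpl35a were among those with the smallest p, and the median was -0.04 without fasted replicate 3 and -0.09 under median-of-ratios scaling. Unlike the mitochondrial score, the ribosomal score overlapped between the diets. It ran from 0.016 to 0.055 in fed and from -0.107 to 0.018 in fasted libraries (exact permutation p = 0.3), lowest in fasted replicate 3.

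**Figure D2:**
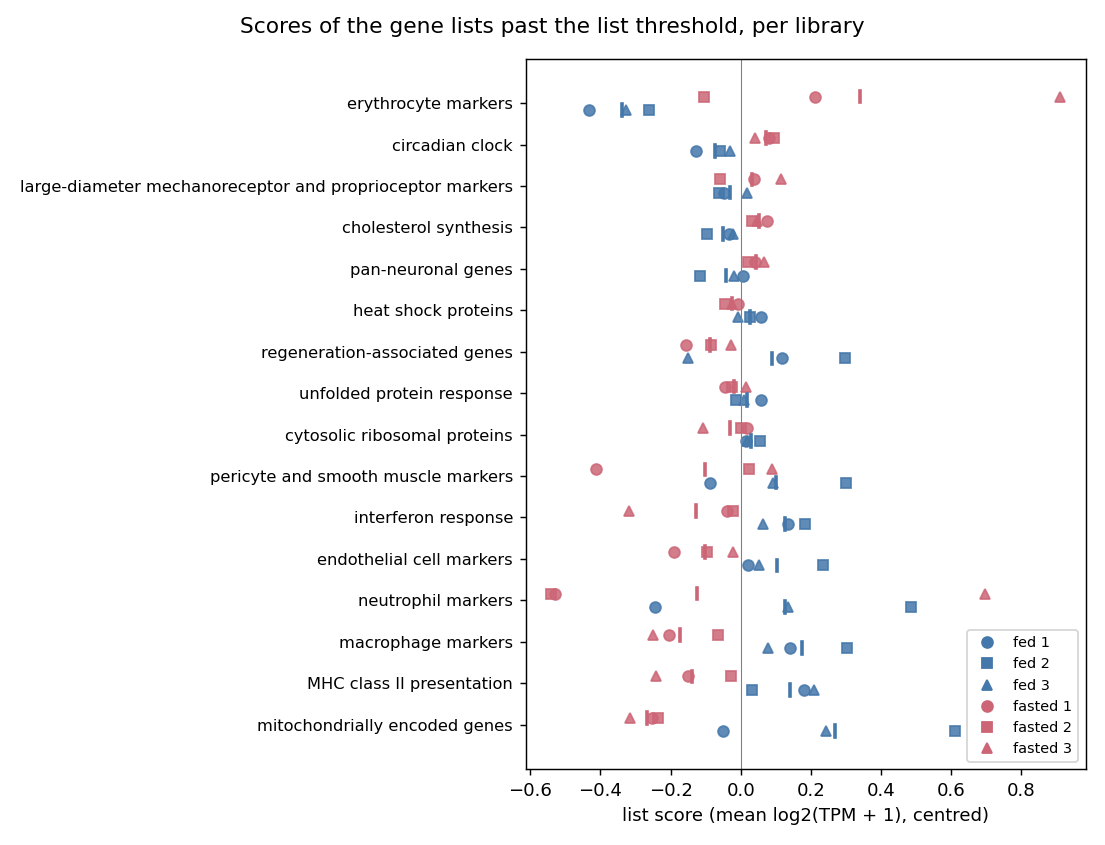
Scores of 16 of the 17 gene lists past the list threshold, as the mean log2(TPM + 1) of the members after centring each gene on the 6 libraries; points are libraries and bars group means, and skeletal muscle is left out for its scale. All 3 fasted libraries lie below the fed ones for the mitochondrial, MHC class II, macrophage, endothelial, interferon and heat shock lists, and above them for the erythrocyte, clock, cholesterol and pan-neuronal lists.

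Cholesterol synthesis and clock genes were higher in fasted libraries. Genes of cholesterol synthesis and uptake rose as a list by a median of 0.09 (limma's camera, adjusted p = 1.2e-05; adjusted p = 0.54 with an estimated correlation), with 20 of 24 higher and 10 passing when adjusted over the list alone. The median was 0.06 under median-of-ratios and quantile scaling, where the list passed too. TPM put the median of all genes at 0.03, against 0.0019 under median-of-ratios and 0.010 under quantile scaling. On TPM, 62.5% of all tested genes were higher in fasted libraries. The 10 genes included Lss (22.1 ± 1.97 against 28.0 ± 1.30 TPM), Insig1 (104.3 ± 3.94 against 122.5 ± 6.56 TPM) and Sc5d (115.9 ± 6.44 against 132.8 ± 1.01 TPM). Clock genes rose by a median of 0.14 (adjusted p = 0.0071; adjusted p = 0.45 with an estimated correlation), with members in both directions when adjusted over the list alone. Per1 (9.24 ± 1.23 against 14.6 ± 1.04 TPM), Cry1, Per3 and Bhlhe40 were higher, and the activator Arntl (log2 fold change -0.53) and the repressor Nr1d1 (-0.30) were lower. No clock or cholesterol gene passed when adjusted over all genes. Glucocorticoid-responsive genes did not pass as a list (median 0.16, adjusted p = 0.13), although 4 of 19 passed when adjusted over the list alone, including Tsc22d3 and Per1, which is also a clock gene. Its median was 0.05 without fed replicate 1 (adjusted p = 0.52), 0.09 without fasted replicate 2 (0.32) and 0.11 without fed replicate 3 (0.22). The list passed without fed replicate 2 (0.18, adjusted p = 0.00046) or fasted replicate 3 (0.11, 0.028), without a filter (0.021) and with array weights (0.029).

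Genes of fatty acid oxidation, a programme that fasting raises in liver, did not pass as a group. Of 26 genes of PPAR-alpha and fatty acid oxidation, 0 passed when adjusted over the list alone, and the list did not pass (median 0.03, mean -0.03, adjusted p = 0.88). Bdh1 was at 43.4 ± 4.81 against 52.0 ± 1.44 TPM. FoxO targets had a median of 0.02 (adjusted p = 0.88), with Pik3ip1 at 70.7 ± 4.72 against 78.5 ± 1.82 TPM and Bcl6 at 22.8 ± 2.19 against 27.2 ± 3.29 TPM. The FoxO median ran from 0.0012 to 0.051 with 1 library left out. Fatty acid synthesis did not pass (0.05, adjusted p = 0.16; Elovl6 and Acsl3 in front), except without fed replicate 2 (adjusted p = 0.018) and without a filter (0.032). The metabolic hormone receptors (0.05, adjusted p = 0.68; Thra and Npy2r) and autophagy and lysosome genes (0.03, adjusted p = 0.70; Bnip3 and Atp6v1a) lists did not pass either. The integrated stress response did not pass (-0.03, adjusted p = 0.065), except without fed replicate 3 (adjusted p = 0.015), with a minimum of 5 TPM (0.011) and under the scalings tried (0.016 to 0.035). Its median ran from -0.066 to -0.032 over the settings with all libraries. The unfolded protein response fell by a median of 0.04 (adjusted p = 0.0061; adjusted p = 0.68 with an estimated correlation). Its members in front were Hsp90b1 (264.5 ± 8.93 against 243.2 ± 0.33 TPM), Sdf2l1, Dnajb11 and Calr, with 0 passing when adjusted over the list alone. Heat shock genes passed in the lower direction (median -0.01, adjusted p = 0.037; adjusted p = 0.54 with an estimated correlation). Its members in front were Hspa1b (18.1 ± 1.80 against 14.1 ± 1.04 TPM), Cryab, Hsph1 and Hspe1, with 0 passing when adjusted over the list alone. The unfolded protein call was lost without fed replicate 1 (median -0.02, adjusted p = 0.11) or fasted replicate 1 (-0.01, 0.058), and the median was -0.06 without fasted replicate 3 and -0.07 under the scalings tried. The heat shock call was lost, with a positive median, without fed replicate 1 (0.02, adjusted p = 0.35) or fasted replicate 2 (0.0033, 0.15). Its median was -0.03 without fed replicate 2, -0.04 without fed replicate 3, and -0.02 without fasted replicate 1 or fasted replicate 3, and -0.04 under the scalings tried. The call was also lost without a filter (adjusted p = 0.13) or without a trend (0.051).

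Neuronal genes were slightly higher in fasted libraries, and the subtypes of sensory neuron had mixed values. Pan-neuronal genes rose by a median of 0.08 (limma's camera, adjusted p = 0.0022; adjusted p = 0.72 with an estimated correlation), with 20 of 21 higher and 0 passing when adjusted over the list alone. In front were Nsg1, Eno2 (573.8 ± 53.0 against 646.7 ± 11.9 TPM), Nsg2 and Thy1. The median was 0.05 under median-of-ratios and TMM-type scaling, where the list passed too, and 0.04 without fed replicate 2, the library with the most muscle RNA. On TPM, 62.5% of all tested genes were higher in fasted libraries. Markers of large-diameter mechanoreceptors and proprioceptors rose by a median of 0.10 (adjusted p = 0.048; adjusted p = 0.80 with an estimated correlation), with Ldhb, Calb1, Scn4b and Scn1a in front and 0 passing when adjusted over the list alone. This call was lost without fed replicate 1 (adjusted p = 0.13), fed replicate 2 (0.21), fasted replicate 1 (0.14) or fasted replicate 3 (0.51), with a median of 0.05 without fed replicate 2 or fasted replicate 3. It was also lost with a minimum of 5 TPM (0.086), without a trend (0.077) or with array weights (0.080). Peptidergic nociceptors (median 0.05, adjusted p = 0.88), non-peptidergic nociceptors and pruriceptors (-0.01, adjusted p = 0.18) and C-fibre low-threshold mechanoreceptors (0.05, adjusted p = 0.56) did not pass. The non-peptidergic list passed in the lower direction without fed replicate 2 (adjusted p = 0.0038) or fasted replicate 2 (0.017). With 1 library left out, the median of the C-fibre list ran from 0.0086 to 0.096. Neuropeptides (median 0.00055, mean -0.03, adjusted p = 0.17; Calcb at 261.6 ± 22.3 against 233.1 ± 5.62 TPM) and sodium and TRP channels (0.06, adjusted p = 0.20; Trpm8 at 22.2 ± 2.01 against 26.0 ± 0.77 TPM) did not pass. The neuropeptide list passed in the lower direction without fed replicate 3 (median -0.11, adjusted p = 0.0015) or fasted replicate 2 (-0.10, 0.0078). Immediate early genes did not pass (0.06, adjusted p = 0.88), with Egr3 at 3.07 ± 0.83 against 5.52 ± 0.10 TPM.

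Among the other cell types, the glia of the ganglion had medians near 0, with members in both directions. Of 16 myelinating Schwann cell markers, 2 were higher and 2 lower at an unadjusted p under 0.05 (limma). The lower ones, without overlap, were Drp2 (75.0 ± 5.28 against 64.6 ± 2.98 TPM) and Ncmap (79.7 ± 4.88 against 71.3 ± 3.50 TPM). Satellite glial markers had a median of 0.02 (adjusted p = 0.88), myelinating Schwann cell markers 0.05 (adjusted p = 0.88), fibroblast markers -0.0017 (adjusted p = 0.28; Lum at 31.9 ± 0.67 against 37.1 ± 0.86 TPM passed when adjusted over the list alone, and Apod was at 1109 ± 33.5 against 976.9 ± 51.0 TPM without overlap) and central glia markers 0.02 (adjusted p = 0.88). Erythrocyte markers rose by a median of 0.73 (limma's camera, adjusted p = 0.00027; adjusted p = 0.54 with an estimated correlation), with 6 of 6 higher. Of these 5 passed when adjusted over the list alone, among them Hba-a1, Hba-a2, Hbb-bt and Hbb-bs. Fasted replicate 3 scored 0.91 against 0.21 and -0.10 in the other fasted libraries, and the alpha-globin genes are near-identical copies that share reads. Skeletal muscle markers fell by a median of 1.86 (adjusted p = 5.7e-08; adjusted p = 0.54 with an estimated correlation), with 12 of 12 lower, 0 passing when adjusted over the list alone and Mb, Atp2a1, Ckm and Actn3 in front. Without fed replicate 2 the median was -0.81. Pericyte and smooth muscle markers fell by a median of 0.11 (adjusted p = 0.0028; adjusted p = 0.66 with an estimated correlation), with Rgs5, Kcnj8, Des and Notch3 in front and 0 passing when adjusted over the list alone. This call was lost without fasted replicate 1 (median -0.03, adjusted p = 0.51), and the median was -0.07 without fed replicate 3 and -0.04 with a minimum of 5 TPM. Des was at 33.9 TPM in fed replicate 2, the library with the most muscle RNA, against 1.67 to 5.57 TPM in the others. Without that library the pericyte and smooth muscle median was -0.08 (adjusted p = 0.045). Neutrophil markers fell by a median of 0.24 (adjusted p = 0.049; adjusted p = 0.80 with an estimated correlation), led by Lcn2, S100a9, Retnlg and Mmp8, with 0 passing when adjusted over the list alone. The neutrophil call was lost without fed replicate 2 (median -0.07, adjusted p = 0.52), fed replicate 3 (-0.17, 0.22), fasted replicate 1 (-0.03, 0.43) or fasted replicate 2 (-0.07, 0.54). It was also lost under the scalings tried (adjusted p from 0.16 to 0.22), without a filter (0.39), without a trend (0.077) or with array weights (0.057), and the median was -0.67 without fasted replicate 3 and -0.43 without fed replicate 1. Lymphocyte (0.07, adjusted p = 0.88), adipocyte (0.01, adjusted p = 0.73), inflammatory cytokine (-0.08, adjusted p = 0.17) and cell cycle lists (0.03, adjusted p = 0.98) did not pass. The cytokine list passed in the lower direction without a filter (median -0.12), and the adipocyte list passed without fasted replicate 1 (0.26, adjusted p = 0.016). With 1 library left out, the lymphocyte median ran from 0.0085 to 0.16 and the cytokine median from -0.18 to -0.031.

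**Figure D3:**
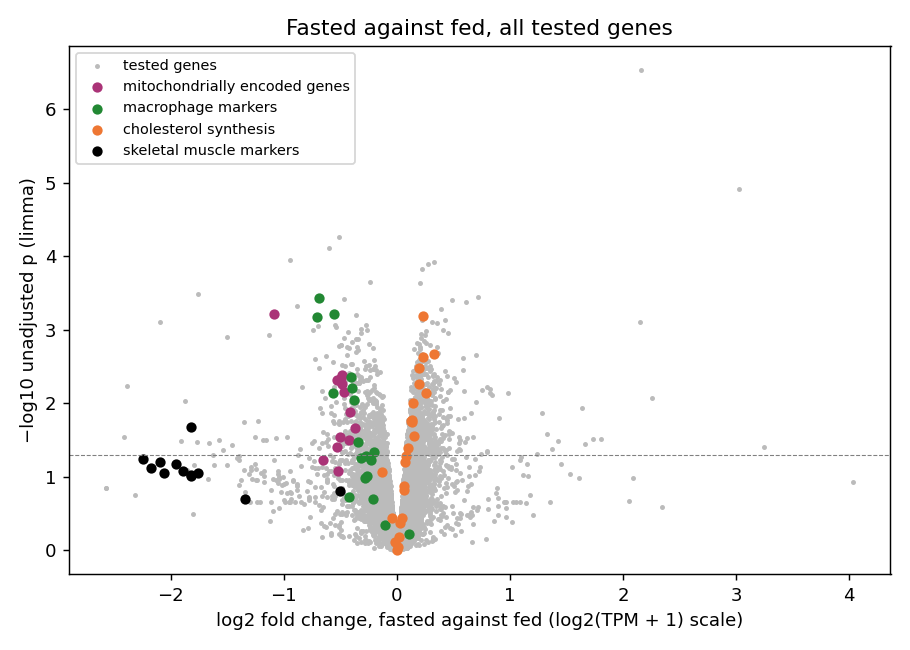
Log2 fold change, fasted against fed, on the log2(TPM + 1) scale (x axis) and -log10 of the unadjusted p from limma (y axis) for the 15097 tested genes, with a dashed line at p of 0.05. Mitochondrial genes and 17 of 18 macrophage genes lie to the left of 0, and 20 of 24 cholesterol genes to the right at smaller fold changes. Skeletal muscle genes lie far to the left near the dashed line.

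In all, 17 of 40 lists passed, 5 higher and 12 lower, with the correlation between genes preset at 0.01. With the correlation estimated for each list, 0 of 40 passed, and 2 had an unadjusted p under 0.05, the macrophage and the clock list. The median of all tested genes was 0.03. Median, mean and test differed in sign for the leptin, FoxO, PPAR-alpha, satellite glia, Schwann, peptidergic, adipocyte, neuropeptide and central glia lists. For the score of a single list, the smallest p an exact permutation test of 3 against 3 can give is 0.1, two-sided, reached by the mitochondrial, macrophage, MHC class II, interferon, endothelial, cholesterol, clock, heat shock, pan-neuronal and erythrocyte lists and, among those that did not pass, the hormone receptor and channel lists.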

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

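Protein-coding genes alone, fry and the counts of which lists lost a call were chosen after seeing the data. The count of 1 changed gene, 1 higher and 0 lower, was 2 changed and 2 higher with a pseudocount of 0.1 or 0.5, where Mir6538 joined Gm23257, and 0 and 0 without a filter, where 29760 genes were tested, or with protein-coding genes alone, which leaves Gm23257 out. Leaving out 1 library gave 1 to 7 changed genes, 1 to 4 higher and 0 to 4 lower; the 7 came without fed replicate 3. The count of 17 lists was 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.22), which tests each list against no change and not against the other genes, and 13 to 18 when a library was left out. Apart from those tests, 11 lists passed in all 19 settings: mitochondrial, ribosomal, macrophage, interferon, MHC class II, endothelial, skeletal muscle, cholesterol, clock, pan-neuronal and erythrocyte. The mitochondrial list had no value with its genes left out. With the replicate number as a block, 1 gene and 17 lists passed, and no list or gene call changed. Deviations of same-numbered libraries correlated at 0.093, 0.11 and 0.066, each the highest for that library, a hint from the data and not the design, so the numbers were not taken as pairs. Of 137 named genes, 128 kept their direction in every setting. The depth is unknown, so no limit from it can be given.

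The sign of these medians and of Gap43 depended on the setting, and the cause was not tested beyond the shift that each scaling applies to all genes. Under median-of-ratios scaling FoxO targets were at -0.0060, autophagy -0.0031, oxidative phosphorylation -0.013, neuropeptides -0.031, satellite glia -0.014, adipocyte -0.018 and central glia -0.0023. Under TMM-type scaling they were at -0.0050, -0.0020, -0.012, -0.030, -0.013, -0.017 and -0.0013. Without mitochondrial genes they were at -0.0072, -0.0043, -0.014, -0.032, -0.015, -0.020 and -0.0037, and the leptin list at -0.00058. Quantile normalization gave -0.0019 for PPAR-alpha, -0.0021 for autophagy, -0.013 for oxidative phosphorylation, -0.016 for neuropeptides, -0.0023 for satellite glia and -0.012 for adipocyte markers. Without a filter neuropeptides were at -0.027 and lymphocyte markers at -0.018. With at least 5 TPM the cell cycle was at -0.012 and adipocyte markers at -0.087. Array weights gave 0.0040 for Gap43, -0.027 for neuropeptides and -0.012 for adipocyte markers.

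Leaving out each library in turn, log2 fold changes ran from -0.086 to 0.038 for Gap43, -0.0035 to 0.16 for Aldh1l1, -0.013 to 0.12 for Aqp4, -0.21 to 0.062 for Sox11, -0.28 to 0.21 for Npy, -0.70 to 0.041 for Car3, -0.14 to 0.055 for Lepr, -0.10 to 0.17 for Socs3 and -0.11 to 0.14 for Gal. List medians ran from -0.086 to 0.024 (regeneration), -0.035 to 0.018 (heat shock), -0.034 to 0.10 (immediate early), -0.044 to 0.031 (non-peptidergic), -0.037 to 0.053 (satellite glia), -0.023 to 0.098 (Schwann), -0.037 to 0.12 (central glia), -0.054 to 0.0080 (integrated stress), -0.0039 to 0.046 (autophagy), -0.11 to 0.067 (neuropeptides), -0.00099 to 0.029 (oxidative phosphorylation), -0.0084 to 0.094 (peptidergic), -0.063 to 0.030 (fibroblast), -0.14 to 0.26 (adipocyte), -0.0022 to 0.033 (leptin), -0.0014 to 0.031 (PPAR-alpha) and -0.0051 to 0.075 (cell cycle).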

Other observations

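Tests chosen only after the result was seen are those on symbol stems, on genes with unadjusted p under 0.05, on glial against macrophage genes, on short transcripts, on nuclear-encoded respiratory genes, on muscle RNA and on glucocorticoid genes. Grouping the tested genes by the letters of their symbols gave 85 stems with at least 15 members, of which 6 passed limma's camera with the preset correlation and 0 with an estimated one. The 16 Snhg genes, which host small nucleolar RNAs in their introns, had a median log2 fold change of -0.15 (adjusted p = 0.00072, but adjusted p = 0.96 with an estimated correlation), and -0.18 under each of the 4 scalings tried. Of the 16, only 1 had an unadjusted p under 0.05, and the exact permutation p of their score was 0.2. The 35 Vps genes of vesicle sorting had a median of 0.07 (adjusted p = 0.030; adjusted p = 0.96 with an estimated correlation), which did not pass under any of these scalings (0.04 each, adjusted p from 0.052 to 0.17). The 32 Col genes of collagens had a median of -0.05 (adjusted p = 0.048; adjusted p = 0.96 with an estimated correlation) and did not pass under them either (adjusted p from 0.21 to 0.32). Among protein-coding genes, median log2 fold changes went from -0.07 for the 90 genes with the shortest transcripts to 0.04 for the 3386 with the longest.

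The 6 libraries make 10 splits, too few for a share under 0.05. The real split gave 1 changed gene against at most 3 in the other splits, a count reached by 5 of the 10; the same held for higher genes, 5 of 10 with at most 3, and the 0 lower genes were reached by 10 of 10. It gave 17 lists, reached by 4 of the 10 splits, with 19 as the highest other. It gave 1501 genes at an unadjusted p under 0.05, reached by 1 of 10, with 919 as the highest other.

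Macrophage and MHC class II genes were lower in the fasted libraries. Glial and fibroblast genes did not fall with them. The macrophage score minus theirs, fasted minus fed, was -0.358 (standard error 0.091), without overlap. This comparison was chosen after the results were seen, so it describes these lists and is no independent test. Endothelial (median -0.22) and pericyte and smooth muscle markers (-0.11) were lower too and were not part of it. A loss of non-neuronal cells other than glia and fibroblasts thus stays open. A single fed library rich in immune cells is argued against as the whole cause by the macrophage median of -0.226 without fed replicate 2. The spread of the macrophage fold changes, 0.146 (scaled median absolute deviation), against a median standard error of 0.127, allows a common factor, which both fewer macrophages and a lower expression per macrophage would give, so the bound set beforehand does not separate them. Fewer macrophages in the ganglia after fasting, fewer carried through the dissociation, and lower expression per cell cannot be told apart, as no count of cells before or after dissociation was used here.

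Mitochondrially encoded genes were lower in the fasted libraries. A bias against short transcripts is argued against by nuclear genes as short as these, ribosomal proteins left out, whose median was -0.00872 (470 genes, bootstrap interval -0.0224 to 0.00065) against -0.49. A lower programme of respiratory genes as a whole is argued against by the nuclear-encoded list, at 0.0183 (interval 0.0073 to 0.030). Both intervals resample genes and not libraries, so they leave out the spread between libraries. The nuclear-encoded median ran from -0.014 to 0.025 over the settings with all libraries, and from -0.00099 to 0.029 with 1 left out. These values lie outside its interval in part but far from -0.49. Muscle RNA in fed replicate 2 is argued against as the whole cause by the median of -0.338 without that library, although it may add to the size. Without that library muscle markers were still lower in fasted libraries (median -0.81), so this does not cover muscle RNA in the other libraries. Muscle RNA in the other libraries, damage to cells during dissociation and an effect of fasting on mitochondrial transcripts stay open and untested.

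Clock genes went both ways in the fasted libraries, with Per1 higher and Arntl lower. For a clock at another phase, the Per2 and Dbp arm minus the Clock and Cry1 arm, without Per1 and Arntl, differed by 0.0452 (standard error 0.052), within the 2 standard errors of 0 set beforehand as the bound against it. That bound was the wrong one, since members of the first arm went both ways (Per3 0.52, Nr1d1 -0.30) and their mean hides this, so a shifted phase stays open. This reading was changed more than once after the value was seen. A glucocorticoid response that raises Per1 was tested on the other genes of the glucocorticoid list, whose score differed by 0.0325 (standard error 0.086). A rise of 0.16, the median of that list, lies within 2 standard errors of this score. Its members also went both ways (Klf9 0.23 and Sgk1 0.46, but Plin4 -0.66), which the mean hides. Of all 19 genes of the list, 6 were higher, Per1 and Tsc22d3 among them, and 1 lower at an unadjusted p under 0.05 (limma). A glucocorticoid response thus stays open.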
